A study of Mus musculus with 576 samples.

How the data were processed

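RNA of 576 single cells was measured, 96 in each of 6 groups formed by treatment (control or LPS) and p27 marker class (high, low or negative), as the labels give them. According to the labels, marrow was flushed from femurs and tibias, red cells were lysed, and single cells were sorted into wells of 96-well plates, amplified by the protocol of Picelli and colleagues and made into Nextera XT libraries. The authors deposited 2 tables of counts, 1 for the 288 control cells and 1 for the 288 LPS cells, and the deposited values are raw counts of reads per gene with no normalization. Per the submitters' processing notes, reads were aligned to mm10 with GSNAP and counted with HTSeq 0.6.0. The annotation release, the strand setting and any read filter are not given in the sources used here. It was checked that the values are whole numbers, that no pair of cells holds identical counts and that the cells' totals differ.

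Each table has 46175 entries per cell, of which 46078 are genes, 92 are ERCC spike-in RNAs and 5 are HTSeq summary counts that name no gene. Of all reads in both tables together, 34.1% were assigned to genes, 2.06% to spike-ins, 52.7% were not aligned, 6.86% fell in no feature and 4.28% were ambiguous. Gene symbols and mm10 coordinates came from the GENCODE M21 annotation by gene ID, which named 45143 of the genes, and 27831 genes had any read. 56 symbols stood on more than 1 entry and were kept apart by ID. Coordinates are 1-based.

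Cells with at least 50000 gene reads and at least 1000 genes were kept, which left 547 cells and removed 29, 12 of them from control p27 high cells. No limit was set on mitochondrially encoded reads, and no clustering or doublet removal was done. As a result 1 control p27 negative cell with 97.9% mitochondrially encoded reads was kept, the only kept cell above 50%. The level of a gene in a group was computed as CPM, the summed reads over kept cells per 1000000 summed gene reads, and a log2 fold as the difference of log2 values after adding 1 CPM. Shares of cells with a gene were computed after thinning every cell to 50000 reads. The G2/M share is the share of cells with at least 5 of 30 listed genes at 1 read or more, and is a score, not a phase call. Where a group had no read of a gene, the fold is a bound against a floor of 3 counts over the group, and where it had 1 to 3 reads the ratio of CPM is given with its exact conditional interval.

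The 9 comparisons were the 3 pairs of p27 classes in each treatment and LPS against control in each class, and the LPS effects of p27 high and p27 negative cells were also subtracted. No test, standard error or count of changed genes was derived from cells, because the cells of a group come from 1 sample as far as the labels say. For 31 gene lists the median log2 fold of members with at least 1 CPM was set against 10000 random lists of the same size drawn from 20 bins of expression, and its percentile is given. Folds were recomputed in 3 parts of each group by cell number, 1 to 32, 33 to 64 and 65 to 96. The median of a list was outside the central range of random lists (percentiles 2.5 to 97.5) and of 1 sign in all parts for 15 lists in the first comparison, p27 high against p27 negative in control. The number was 7 for p27 high against low and 12 for p27 low against negative in control, 13, 9 and 12 for the same pairs under LPS, 10, 10 and 14 for LPS against control in p27 high, low and negative cells, and 4 for the difference.

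Named genes had at least 10 CPM in the higher group, at least 1 read without thinning in at least 20% of its kept cells and the same direction in summed CPM, in the mean of per-cell CPM and in each of the 3 parts, and they were ranked by the smallest absolute log2 fold over the parts. The first 10 each way were taken for p27 high against p27 negative in control and for LPS against control in p27 high and in p27 negative cells, and the first 5 each way elsewhere. Up to 4 members of each list with the largest absolute log2 fold and 10 genes of the cell cycle and the sorting gate were added. The groups, comparisons, lists, filters, naming rule and all but 1 of the alternatives were fixed before the data were examined. Which lists are described at length, which values count as main results and the alternative restricted to cells numbered 33 to 96 were chosen after list values had been seen.

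Alternatives were the mean of per-cell CPM, TMM factors from edgeR 4.0.16 (1.08, 1.05, 1.02, 0.987, 0.941 and 0.932 for the 6 groups), totals without mitochondrially encoded genes, all cells with a read, cells with at least 200000 reads and 2000 genes, cells with at most 10% mitochondrially encoded reads, leaving out the top cell of each gene, single parts of the cells, 0.1 or 5 CPM added, and list members with any read or at least 10 CPM. Shares were recomputed at 200000 reads per cell, without thinning, with at least 5 reads, and with at least 3 or 8 G2/M genes. The procedure was tested on simulated data in which 200 of 46078 genes were changed. In simulated p27 high against p27 negative control cells the median recovered log2 fold was -1.95, -0.97, 0.89 and 1.94 for true values of -2, -1, 1 and 2, and in simulated LPS against control p27 high cells it was -1.96, -1.01, 1.1 and 2.01. The share of genes within 0.5 of the true value was 58 to 80% for changed genes, and 72.8% and 65.4% for unchanged genes of at least 10 CPM in the 2 simulations, so the fold of a single gene can be off by more than that. Of 200 unchanged lists 12 and 8 fell outside the central range. The simulated genes varied independently of each other, so this rate does not cover lists whose members vary together within cells. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.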

Results

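Single haematopoietic stem cells (HSCs) from mouse bone marrow were profiled by RNA sequencing, 1 library per cell. The cells had been sorted as CD150-positive, CD48-negative, cKit-positive and Sca1-positive, a phenotype enriched for long-term HSCs. They came from control marrow or from marrow after lipopolysaccharide (LPS), a bacterial cell wall component that triggers innate immune signalling. Within each treatment the cells were divided by a p27 marker into high, low and negative classes, and the series title presents the marker as one of G0, the resting state outside the cell cycle. Each of the 6 groups held 96 cells. The sources used here do not give the number of animals, the LPS dose or the time after it, so each group counts as 1 sample and no difference between groups was tested. After cells with few reads or genes were left out, 84, 93 and 95 control cells remained in the p27 high, low and negative classes, and 93, 90 and 92 LPS cells.

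The kept cells held between 52163 and 1942773 gene reads each. The median was 229696, 224003 and 390369 reads in control p27 high, low and negative cells, and 284633, 287584 and 439918 in the LPS classes. Summed over a group the reads came to 21714440, 30435191, 41583206, 33295314, 27775306 and 49018367 in the same order. At an equal depth of 50000 reads the median cell had 3932, 4164 and 4863 detected genes in the control classes and 3985, 3961 and 4922 in the LPS classes, so p27 negative cells had the most genes under both treatments. Levels are counts per 1000000 (CPM) of a group's summed reads with exact 95% Poisson intervals in parentheses, and shares of cells carry 95% Clopper-Pearson intervals. The Poisson intervals cover the counting of reads only, and reads are not molecules, since the libraries have no molecular identifiers. The Clopper-Pearson intervals cover the drawing of cells only, as if cells were independent, and the cells of a group are not replicates. Beside the main log2 folds, ranges are given over 3 parts of each group by the cell number in the labels (1 to 32, 33 to 64 and 65 to 96), which are not replicates either. Most list medians are given with their percentile among 10000 random lists of genes of similar level.

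Cell cycle genes were compared first across all 6 groups. Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361 in mm10), which encodes the proliferation antigen Ki-67, had 11.6 (10.2 to 13.1) CPM in control p27 high cells, 64.2 (61.4 to 67.1) in p27 low cells and 804 (795 to 812) in p27 negative cells. Over the 3 parts of control p27 negative cells its level ran from 524 to 1239 CPM, far outside that interval. Under LPS the same gene had 15.3 (14 to 16.7), 36.3 (34.1 to 38.6) and 656 (649 to 663) CPM. Cdkn1b (ENSMUSG00000003031, chromosome 6, 134920401 to 134925513), the gene of the CDK inhibitor p27, had 74.6, 68.5 and 81.9 CPM in the control classes, so its transcript did not follow the marker there. Under LPS Cdkn1b stood at 108 (104 to 111) CPM in p27 high cells against 62.9 and 74.9 in p27 low and negative cells. Cdk6 (ENSMUSG00000040274, chromosome 5, 3341485 to 3531008), a kinase of G1 progression, had 334 (326 to 342), 618 (609 to 627) and 626 (619 to 634) CPM in the control classes and 462, 1038 and 807 under LPS, the lowest value in p27 high cells each time. Its relative Cdk4 (ENSMUSG00000006728, chromosome 10, 127063534 to 127067920) varied less, from 737 CPM in LPS p27 high to 944 in control p27 negative cells. Ccnd2 (ENSMUSG00000000184, chromosome 6, 127125162 to 127152193), a D-type cyclin, ran the other way in control cells, with 838 (825 to 849.8) CPM in p27 high and 337 (331 to 342) in p27 negative cells. Ccnd1 (ENSMUSG00000070348, chromosome 7, 144929931 to 144939925) had 25.9, 52.3 and 16.7 CPM in control and 44.6, 11.1 and 8.79 CPM in LPS cells.

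**Figure D1:**
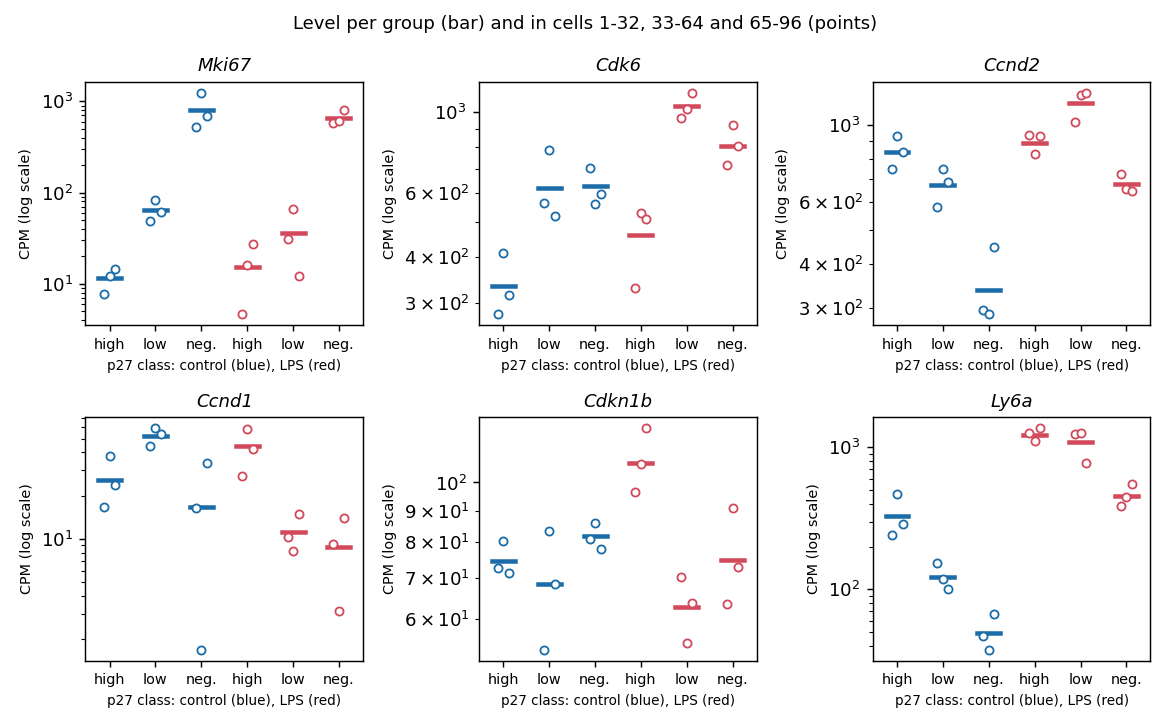
Levels in CPM on a log axis of Mki67, Cdk6, Ccnd2, Ccnd1, Cdkn1b and Ly6a in the 6 groups, with a line at the level of each group and a point for each of its 3 parts by cell number. Mki67 lay at 804 CPM in control p27 negative cells and at 11.6 CPM in control p27 high cells, while Ly6a lay at 331 CPM in control p27 high and at 1220.3 CPM in LPS p27 high cells.

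Among the genes of the sorting gate, Ly6a (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031), which encodes Sca-1, differed most. It had 331 (323 to 339), 122 and 49.7 CPM in the control classes and 1220.3 (1208 to 1232), 1090.4 and 455 CPM under LPS. Kit (ENSMUSG00000005672, chromosome 5, 75574916 to 75656722) had 402, 542 and 337 CPM in control and 308, 318 and 213 CPM in LPS cells. Slamf1 (ENSMUSG00000015316, chromosome 1, 171767127 to 171801184), the gene of CD150, ranged from 52.5 to 106 CPM. Cd48 (ENSMUSG00000015355, chromosome 1, 171682009 to 171705258), whose product is absent from the surface of the gated cells, stayed between 3.96 and 17.5 CPM.

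p27 high and p27 negative control cells were compared to ask which transcripts separate cells with the most and the least G0 marker. Mitotic genes separated them most. All 30 measured genes of the G2/M list were lower in p27 high cells, with a median log2 fold of -4.42 (-5.38 to -4.14 over the parts, percentile 0). Birc5 (ENSMUSG00000017716, chromosome 11, 117849251 to 117855743), which encodes the mitotic regulator survivin, had 2.39 CPM (1.79 to 3.14) against 297 CPM (291 to 302), a log2 fold of -6.45. Ccnb2 (ENSMUSG00000032218, chromosome 9, 70407692 to 70421547), a mitotic cyclin, had 4.79 CPM (3.91 to 5.8) against 509 CPM (502 to 516), and its reads were found in 25% and 85.3% of cells at equal depth. In the other direction stood markers of dormant and long-term HSCs, of which 35 of 40 were higher in p27 high cells with a median of 0.89 (0.76 to 1.2, percentile 100).

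The 10 ranked genes on the lower side of p27 high cells were Birc5, Ccnb2, Knl1, Kif11, Bub1, Kif20a, Ube2c, Ncapg, Esco2 and Foxm1, of which Birc5, Ccnb2, Kif11, Bub1, Kif20a and Ube2c are members of the G2/M list. Their log2 folds ran from -5.87 to -6.46. Genes of DNA replication were lower to a smaller degree, 28 of 30 S-phase genes with a median of -0.84 (-1.57 to -0.53, percentile 0). Rrm2, a subunit of ribonucleotide reductase, had a log2 fold of -4.32 and the replication factor Cdc45 one of -2.81, whereas the uracil-DNA glycosylase gene Ung was higher, at 80.2 against 12.7 CPM. Cyclins, CDKs and their inhibitors were mixed, 8 higher and 14 lower of 22, with a median of -0.37 (-0.48 to -0.38, percentile 0.67). Within that list Cdkn1c, the gene of the inhibitor p57, was higher with a log2 fold of 1.59 (1.21 to 2.01), and Cdkn2c, the gene of p18, was lower with -2.41 (-3.22 to -1.98).

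The 10 ranked genes on the higher side were Pygm, Sult1a1, Gm16565, Gm45837, Hif3a, Procr, Clcf1, Ctsh, Clip3 and Trib3, with log2 folds from 3.23 to 5.8. Pygm (ENSMUSG00000032648, chromosome 19, 6384399 to 6398459), the muscle isoform of glycogen phosphorylase, had 92.4 CPM (88.4 to 96.5) against 0.673 CPM (0.447 to 0.973). Sult1a1 (ENSMUSG00000030711, chromosome 7, 126672865 to 126676432), a sulfotransferase gene used as a marker of long-term HSCs, had 354 CPM (346 to 362) against 10.8 CPM (9.82 to 11.8) and was detected in 50% and 12.6% of cells. Procr (ENSMUSG00000027611, chromosome 2, 155751117 to 155755471), the gene of the endothelial protein C receptor EPCR, had 228 CPM (221 to 234) against 16 CPM (14.8 to 17.3). Cish (ENSMUSG00000032578, chromosome 9, 107296026 to 107302784), a cytokine-induced inhibitor of STAT5 signalling, had 264 against 36.6 CPM. Gm16565 is annotated as a processed transcript, and the sources do not give the strand setting of the counts, so its reads could not be assigned with certainty. For Hif3a 1 cell held most of the few reads in p27 negative cells.

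Immediate early and stress genes were higher in p27 high cells, 18 of 22 with a median of 0.95 (percentile 100). Their part medians ran from -0.027 to 1.17, and the median was 0.58 in cells with at least 200000 reads. Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) had 1739 against 538 CPM. Glycolysis genes were higher in 16 of 23 cases with a median of 0.41 (0.15 to 0.67, percentile 99), and the median was 0.17 in the cells with at least 200000 reads and 0.26 with each cell weighted equally. Aldoa (ENSMUSG00000030695, chromosome 7, 126795234 to 126800751), an aldolase gene, had 1017 against 336 CPM and its paralog Aldoc 94.2 against 5.89. Nuclear genes of oxidative phosphorylation moved the other way, 40 of 43 lower with a median of -0.4 (-0.57 to -0.41, percentile 0). Uqcrq, a complex III subunit, had 74 against 141 CPM, and Atp5o, a subunit of ATP synthase, 97.4 against 184.

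Because the series title names cytoplasmic calcium, genes of calcium channels, pumps and stores were compared as a group. 22 of 36 were higher in p27 high control cells, with a median of 0.39 (0.086 to 0.41, percentile 99.2), which became 0.25 when the cell with the highest CPM of each gene was left out. Orai1 (ENSMUSG00000049686, chromosome 5, 123015074 to 123030456), the pore subunit of store-operated calcium entry, had 116 CPM (112 to 121) against 42 CPM (40 to 44) and its relative Orai3 212 against 87.5 CPM. Calcium sensors and calcium-dependent signalling genes had a median of 0.13, with 21 of 36 higher (percentile 75). Megakaryocyte and platelet genes were lower in p27 high cells in 12 of 17 cases, with a median of -0.69 (-1.08 to -0.48, percentile 0.030). Pf4 (ENSMUSG00000029373, chromosome 5, 90772435 to 90773383), the gene of platelet factor 4, had 87.8 CPM (83.9 to 91.9) against 687 CPM (679 to 695), and the platelet glycoprotein gene Gp1ba 1.57 against 36 CPM. All 11 measured erythroid genes were lower, with a median of -1.88 (-2.78 to -0.44), among them the transcription factor gene Gata1 at 24.8 against 182 CPM. The megakaryocyte median was -1.01 without the top cell of each gene, and 1 cell held 57.8% of the Pf4 reads of the p27 high class.

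**Figure D2:**
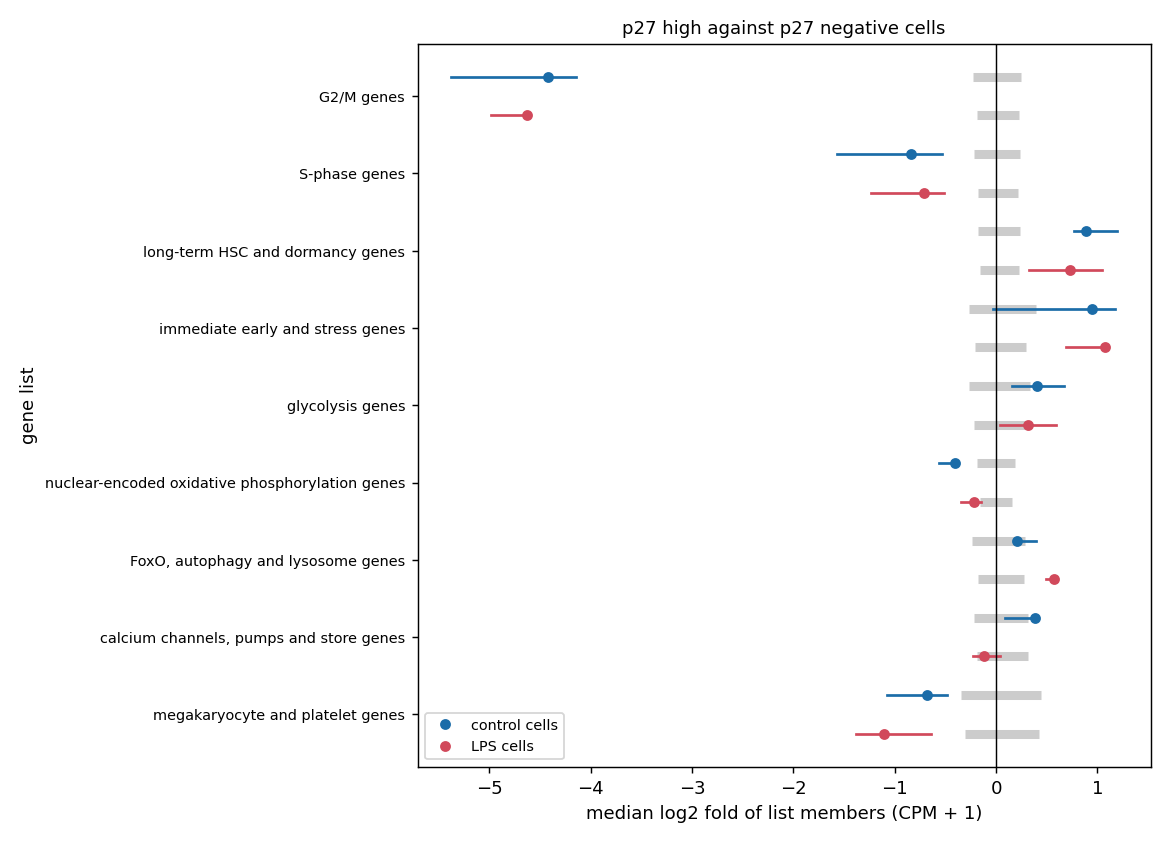
Median log2 fold of p27 high against p27 negative cells for 9 gene lists, with control cells in blue and LPS cells in red. Dots mark the median from summed reads, coloured lines the range of the 3 parts by cell number and grey bars the central 95% of random lists, and the G2/M medians of -4.42 and -4.63 stand farthest from 0.

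Single cells were also scored by how many of the 30 G2/M genes they contained at equal depth. The share with at least 5 of these genes was 69% (58 of 84 cells, 58 to 78.7%) in control p27 high cells, 62.4% (58 of 93 cells, 51.7 to 72.2%) in p27 low cells and 96.8% (92 of 95 cells, 91 to 99.3%) in p27 negative cells. Under LPS it was 61.3% (57 of 93 cells, 50.6 to 71.2%), 60% (54 of 90 cells, 49.1 to 70.2%) and 95.7% (88 of 92 cells, 89.2 to 98.8%). The median cell held 6, 6 and 22 of the genes in control and 5, 5 and 22 in LPS cells. Cells with 4 or 5 genes, next to the limit, numbered 20, 29, 5, 22, 38 and 2 in the 6 groups. Over the 3 parts by cell number the share ran from 47.8 to 84.4% in control p27 high, 46.7 to 77.4% in p27 low and 90.6 to 100% in p27 negative cells, and from 43.8 to 87.5%, 50 to 74.2% and 92.9 to 96.9% under LPS. The difference between the classes depends on depth and on the limit. Among cells thinned to 200000 reads the share was 97.9%, 88.9% and 97.1% in the control classes and 90.1%, 93.8% and 98.8% in the LPS classes, and without thinning it was 98.8%, 100% and 98.9% and 100%, 100% and 98.9%. When a gene had to have at least 5 reads without thinning, the share was 20.2% in control p27 high, 15.1% in control p27 low, 90.5% in control p27 negative, 17.2% in LPS p27 high, 13.3% in LPS p27 low and 92.4% in LPS p27 negative cells. A few reads of a gene may be stray reads or low transcription, so they are weak evidence in these tables. Genes chosen for at least 200 reads in 1 cell and under 5 in all others of its table were traced. They had 1 to 4 reads in 2.21% of the other control cells and 1.96% of the other LPS cells. In the other table the same genes had such reads in 1.85% and 0.677% of cells, so the 2 sources cannot be told apart.

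p27 high and p27 low control cells were compared to ask whether the level of the marker, and not only its presence, separates cells. The difference in mitotic genes was small beside that from p27 negative cells. Of 29 measured G2/M genes 13 were higher and 16 lower in p27 high cells, with a median of -0.4 (-0.93 to 0.52, percentile 0.60), and the median was -0.017 without the top cell of each gene and -0.1 with cells weighted equally. Mki67 itself was lower in all parts, with a log2 fold of -2.38 (-2.68 to -2.01), but 1 cell held 35.4% of its p27 low reads. At equal depth Mki67 was found in 41.7% (31 to 52.9%) of p27 high and 46.2% (35.8 to 56.9%) of p27 low cells. At least 5 reads without thinning lay in 11.9% (5.86 to 20.8%) and 22.6% (14.6 to 32.4%), and the intervals overlap both times. Long-term HSC and dormancy genes were higher in 28 of 40 cases, with a median of 0.4 (0.14 to 0.64, percentile 99.99). Sult1a1 had 354 CPM (346 to 362) in p27 high against 60.5 CPM (57.8 to 63.3) in p27 low cells, and Procr 228 against 93.1 CPM. The von Willebrand factor gene Vwf, a marker of platelet-biased HSCs, went the other way with 55.5 against 158 CPM, although its part log2 folds ran from -2.19 to 0.17.

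Platelet and erythroid genes again were lower in p27 high cells. The megakaryocyte and platelet list had 12 of 17 genes lower and a median of -0.76 (-2.42 to -0.5, percentile 0), with Gp1ba at 1.57 against 37.5 CPM. The erythroid list had 8 of 9 lower and a median of -1.65 (-2.02 to -0.82). Tpm4, a tropomyosin gene, and F2rl2, the gene of the thrombin receptor PAR3, were among the 5 ranked genes on the lower side, with log2 folds of -4.71 and -4.09, beside Zfp566, Gp1ba and Khnyn. Ranked genes on the higher side included Piga, Tns2, Satb1 and Jakmip1, with log2 folds from 2.75 to 3.57. Piga, which acts in the synthesis of glycosylphosphatidylinositol anchors, had 30 against 1.61 CPM. Genes of oxidative phosphorylation were lower in 37 of 43 cases with a median of -0.29 (-0.29 to -0.24, percentile 0.010).

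Control p27 low and p27 negative cells differed in mitotic genes nearly as much as p27 high and negative cells did. All 30 measured G2/M genes were lower in p27 low cells, with a median of -3.66 (-5.0 to -3.8, percentile 0), and 28 of 30 S-phase genes were lower with a median of -1.15 (-1.79 to -0.21, percentile 0). Nuf2, a kinetochore component, had 1.08 against 139.8 CPM, and the mitotic kinase gene Plk1 0.953 against 143. They ranked among the first 5 lower genes with Neil3, Bub1 and Knl1, whose log2 folds together ran from -5.99 to -6.51. Tyms, the thymidylate synthase gene, had 61.1 against 309 CPM. Dormancy genes were higher in 30 of 39 cases with a median of 0.49 (0.44 to 0.72, percentile 100). Fgd5 (ENSMUSG00000034037, chromosome 6, 91978878 to 92076004), whose expression marks HSCs, had 43.8 against 6.25 CPM and Procr 93.1 against 16. The ranked genes on the higher side were Alkbh2, Samd10, Zbed5, 1700030K09Rik and Lat2, with log2 folds from 2.37 to 3.8. Megakaryocyte and platelet genes did not follow this contrast, with a median of -0.064 and 8 of 15 lower.

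The same contrast between p27 high and p27 negative cells was made among cells from LPS marrow. These classes were gated after LPS, so the contrast cannot show whether the classes of control marrow stay apart. Mitotic genes were lower in p27 high cells to a similar degree as in control, all 30 of them, with a median of -4.63 (-4.98 to -4.63, percentile 0). The ranked lower genes were Ccnb2, Ube2c, Plk1, Cenpf and Pimreg, with log2 folds from -5.89 to -6.98, and Ccnb2 had 2.22 CPM (1.75 to 2.79) against 407 CPM (401 to 413). Dormancy genes were higher in 33 of 40 cases, with a median of 0.73 (0.33 to 1.04, percentile 100). Sult1a1 led the ranked higher genes, at 315 CPM (309 to 321) against 18.4 CPM (17.2 to 19.7), followed by Ackr1, Ms4a4c, Ldhd and Chrnb1. Procr had 89.4 against 17.4 CPM. The dormancy median was 0.33 in cells numbered 33 to 64, and 1 cell held most of the Ackr1 reads in each class.

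Immediate early and stress genes were higher in LPS p27 high cells, 19 of 23 with a median of 1.08 (0.69 to 1.07, percentile 100). Egr1, an early response transcription factor gene, had 467 against 111 CPM and the nuclear receptor gene Nr4a1 89.1 against 12.4. Genes of FoxO signalling, autophagy and lysosomes were higher in 29 of 32 cases with a median of 0.58 (0.5 to 0.6, percentile 100). Among them Sqstm1, the gene of the autophagy receptor p62, had 613 against 228 CPM, Map1lc3b 352 against 128 and the lysosomal protease gene Ctsl 138 against 36.7. In control cells that list had a median of 0.21 with 22 of 31 higher (percentile 92.2). Interferon-gamma response and antigen presentation genes were nearly level as a list, with a median of 0.092 and 20 of 34 higher (percentile 82.4). Among its members Cd74, the MHC class II invariant chain gene, stood at 858 against 135 CPM and H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823) at 116 against 23.5. Calcium channel, pump and store genes had a median of -0.12 (-0.23 to 0.041, percentile 7.77). Megakaryocyte and platelet genes were lower in 11 of 15 cases with a median of -1.11 (-1.39 to -0.64, percentile 0), and Pf4 had 67.6 against 471 CPM. That median was -0.74 with 5 CPM added before the logarithm.

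p27 high and p27 low LPS cells differed in HSC genes and in interferon genes, in opposite directions. Dormancy genes were higher in p27 high cells in 32 of 39 cases, with a median of 0.68 (0.6 to 1.13, percentile 100). Hlf (ENSMUSG00000003949, chromosome 11, 90336536 to 90390895), a transcription factor gene of HSCs, had 171 CPM (167 to 176) against 27.8 CPM (25.9 to 29.9), and Fgd5 had 16.3 against 0.324 CPM. Type I interferon response genes were lower in 33 of 40 cases, with a median of -0.27 (-0.41 to -0.13, percentile 0) that became -0.44 with cells weighted equally. Usp18, a deubiquitinase gene that limits interferon signalling, had 385 against 736 CPM.

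The ranked higher genes were H2-Aa, Sult1a1, Cenpu, Lhcgr and Uhrf1bp1, with log2 folds from 3.52 to 4.43, and H2-Aa had 116 against 4.39 CPM. The ranked lower genes were Mfsd2b, Gata1, Pde10a, AW011738 and Ksr1, with log2 folds from -1.87 to -4.79. Gata1 had 8.95 against 130.4 CPM and Mfsd2b, a lipid transporter gene of erythrocytes and platelets, 6.7 against 134. The megakaryocyte and platelet list moved with them, with a median of -1.1 and 10 of 15 lower (-1.52 to -0.079, percentile 0). FoxO, autophagy and lysosome genes were higher in 25 of 32 cases, with a median of 0.44 (0.18 to 0.62, percentile 99.98), including the lysosomal protease gene Ctsb with a log2 fold of 0.95. Glycolysis genes were higher in 17 of 23 cases with a median of 0.44 (0.42 to 0.51, percentile 99.92). The G2/M list had a median of 0.2 (-0.095 to 0.79, percentile 66.6), within the range of random lists.

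p27 low and p27 negative LPS cells were far apart in mitotic genes and nearly level in dormancy genes. All 30 measured G2/M genes were lower in p27 low cells with a median of -4.87 (-5.54 to -4.95, percentile 0). The ranked lower genes were Ccna2, Nuf2, Cdca8, Cdca5 and Ube2c, with log2 folds from -6.49 to -6.72, and the cyclin A gene Ccna2 had 3.78 against 501 CPM. The dormancy list had 21 genes higher and 19 lower of 40 and a median of 0.072 (-0.14 to 0.078, percentile 67.9), which turned to -0.089 with cells weighted equally. Within it Gfi1b, a transcription factor gene of HSCs and of megakaryocyte and erythroid cells, had 158 against 66.8 CPM, whereas Hlf had 27.8 against 53.7. Type I interferon response genes were higher in 35 of 40 cases with a median of 0.38 (0.26 to 0.55, percentile 100). Ifit3, an interferon-induced antiviral gene, had 298 against 73 CPM and Slfn5 113 against 15. The other ranked higher genes were Lcn2, Ms4a4b, Sipa1l3 and Slc25a15, and for Ms4a4b 1 cell held most of the reads.

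The comparison of LPS with control in p27 high cells asked which transcripts differ between the cells with the most G0 marker in the 2 treatments. Each p27 class was gated within its treatment. Cells that changed class and cells that changed expression therefore cannot be told apart in any class. All 40 measured type I interferon response genes were higher under LPS, with a median log2 fold of 2.8 (2.2 to 3.3, percentile 100). Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), an interferon-induced chemokine gene, had 5745 CPM (5719 to 5770.5) against 1.52 CPM (1.05 to 2.13) and was found in 96.8% of LPS and 1.19% of control cells, where 1 cell held all of its reads. Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981), the gene of the inflammatory cytokine interleukin 6, had 222 CPM under LPS and no read in control, so it was at least 1609-fold higher against a floor of 3 counts over the group. Long-term HSC and dormancy genes were lower in 33 of 40 cases, with a median of -0.52 (-0.7 to -0.39, percentile 0).

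The ranked higher genes were Cxcl10, Cxcl11, Ccl5, Ifit3, Rsad2, Il6, Gm10851, Ifi204, Ifit1 and Cmpk2. Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518), the gene of the chemokine RANTES, had 2363 against 1.57 CPM, and Rsad2 (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452), the gene of the antiviral enzyme viperin, 2571 against 8.43. Ifit3 (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731) had 284 CPM against 1 read in control, a ratio of 6170.2 (1107 to 243737). Ifi204, with no control read, was at least 719-fold higher. Cxcl11 (ENSMUSG00000060183, chromosome 5, 92359544 to 92365485), also without a control read, was at least 7576-fold higher, but the annotation calls it a polymorphic pseudogene. Gm10851 is annotated as antisense RNA, so its reads could not be told from reads of the opposite strand. Interferon-gamma response genes were higher in 33 of 34 cases with a median of 1.12 (1.28 to 1.34 over the parts), with the immunity-related GTPase gene Iigp1 at 542 against 16.3 CPM. Toll-like receptor and NF-kB genes were higher in 31 of 33 cases with a median of 1.62 (1.3 to 2.89, percentile 100). Cytokine and STAT3 response genes were higher in 18 of 22 cases with a median of 0.92 (0.37 to 0.83, percentile 100), among them Cebpd, a transcription factor gene of the acute phase response, at 154 against 4.24 CPM. That median was 0.52 in cells numbered 33 to 96, a subset chosen after the data were seen.

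Lower genes under LPS in p27 high cells included regulators of HSCs. Gfi1b (ENSMUSG00000026815, chromosome 2, 28609450 to 28621982) had 46.6 CPM (44.3 to 49) against 139 CPM (134 to 144), and Tek (ENSMUSG00000006386, chromosome 4, 94739289 to 94874976), the gene of the angiopoietin receptor TIE2, 17.9 against 51.3 CPM. In the same list Egr1 was higher, at 467 against 83.5 CPM. The ranked lower genes were Snx32, Ankrd13d, Zfp30, Ccdc166, Sdc2, Limk1, Myl10, Osgin1, 2610008E11Rik and Lsm11, with log2 folds from -2.16 to -4.87, and Ccdc166 had 17 against 124 CPM. Calcium channel, pump and store genes were lower in 28 of 36 cases with a median of -0.58 (-0.95 to -0.22, percentile 0.030). Itpr3, an IP3 receptor gene of the endoplasmic reticulum, had 0.691 against 19.1 CPM. The calcium median was -0.38 in cells with at least 200000 reads. Ribosome biogenesis and MYC target genes were higher in 24 of 33 cases with a median of 0.34 (0.15 to 0.33, percentile 99.99). Megakaryocyte and platelet genes had a median of -0.63 with 12 of 17 lower (-0.78 to -0.19). Scaling to total reads set the median log2 fold of all genes at -0.095, -0.16 and -0.12 for LPS against control in p27 high, low and negative cells, and with TMM factors it was 0.028, -0.011 and -0.0068. Control and LPS cells were counted in separate tables, so treatment and any difference between runs or plates cannot be told apart in any LPS against control comparison. This weighs most on small shifts such as the dormancy medians.

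**Figure D3:**
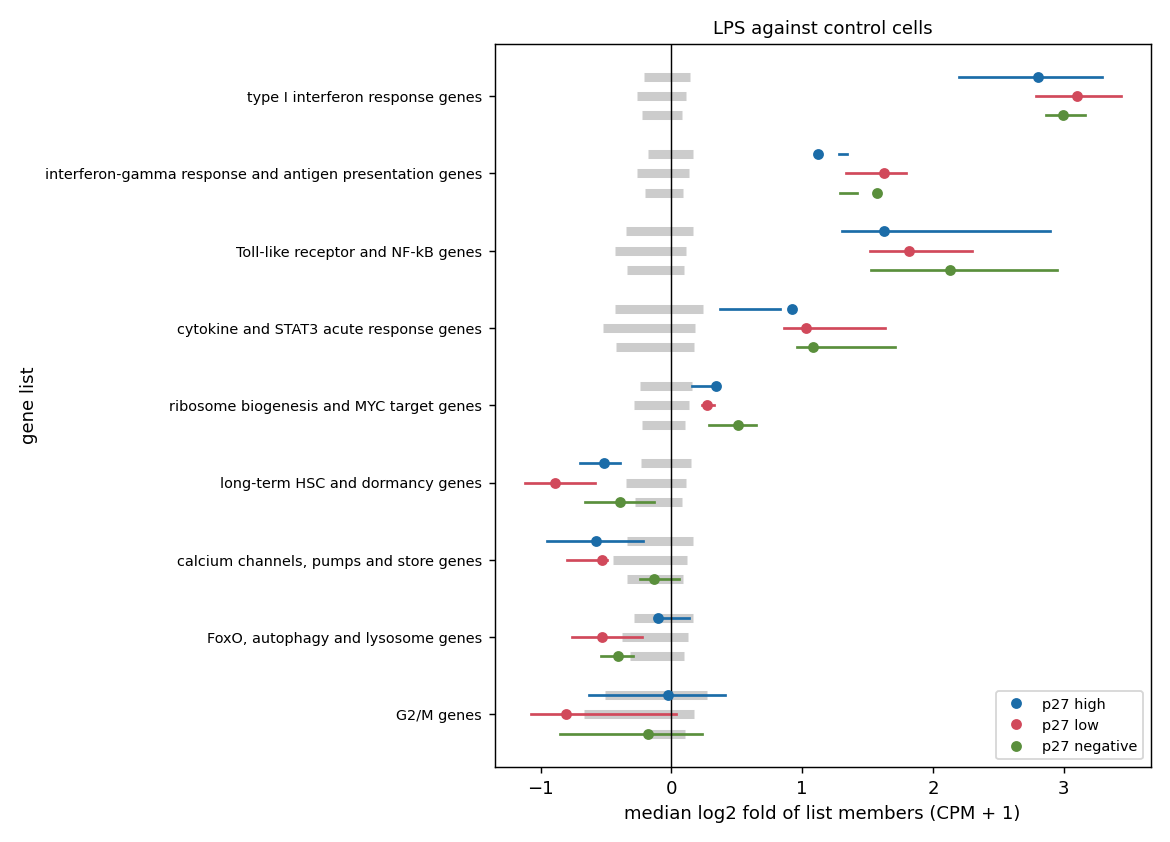
Median log2 fold of LPS against control for 9 gene lists, with p27 high cells in blue, p27 low cells in red and p27 negative cells in green. Dots mark the median from summed reads, coloured lines the range of the 3 parts by cell number and grey bars the central 95% of random lists, and the type I interferon medians of 2.8, 3.1 and 3.0 stand highest.

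In p27 low cells LPS went with higher interferon genes and lower HSC genes. All 40 type I interferon response genes were higher, with a median of 3.1 (2.79 to 3.44, percentile 100), and 31 of 33 Toll-like receptor and NF-kB genes with a median of 1.82 (1.52 to 2.3, percentile 100). Ccl5 and Cxcl9, the gene of another interferon-induced chemokine, had no control read and were at least 27338-fold and 7347-fold higher. Dormancy genes were lower in 32 of 39 cases, with a median of -0.89 (-1.12 to -0.59, percentile 0). Fgd5 had 0.324 CPM (0.148 to 0.615) against 43.8 CPM (41.5 to 46.2), Hlf 27.8 CPM (25.9 to 29.9) against 164 CPM (160.0 to 169), and Esam (ENSMUSG00000001946, chromosome 9, 37528078 to 37538319), an adhesion molecule gene expressed on HSCs, 92.9 against 365 CPM. The other ranked lower genes were D630039A03Rik, Tmco3, Gria3 and Scml4, with log2 folds of -4.05 to -5.29, and the ranked higher genes were Ccl5, Cxcl11, Cxcl10, Cxcl9 and Serpina3f. Calcium channel, pump and store genes were lower in 26 of 33 cases with a median of -0.53 (-0.8 to -0.5, percentile 0.69), and the median was -0.18 when list members with any read were included. The calcium pump gene Atp2b4 had 34.1 against 121 CPM and the ATP-gated channel gene P2rx1 42.3 against 174.

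p27 negative cells, the class with the most mitotic transcripts, were compared last. All 40 type I interferon response genes were higher under LPS, with a median of 3.0 (2.87 to 3.16, percentile 100). Cxcl10 had 7749.9 CPM (7725 to 7775) against 2.77 CPM (2.28 to 3.32). Mx1 (ENSMUSG00000000386, chromosome 16, 97447035 to 97462907), an antiviral GTPase gene, had 181 CPM against 1 read in control, a ratio of 7523 (1349.9 to 297171). Cxcl9 had 564 CPM and no control read, so it was at least 7818-fold higher, and Il6 was at least 403-fold higher at 29.1 CPM. Dormancy genes were lower in 24 and higher in 16 of 40 cases, with a median of -0.39 (-0.66 to -0.13, percentile 0.15). Tek had 23 against 67.8 CPM, whereas Cish was higher at 247 against 36.6.

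The remaining ranked higher genes in p27 negative cells were Cxcl11, Gm10851, Tm4sf1, Mx2, Ccl5, Gm12185 and Serpina3f. Cxcl11 had 1 read in control, a ratio of 44308 (7952 to 1750130), and Tm4sf1 2 reads, a ratio of 2142 (593 to 17689). Mx2, also annotated as a polymorphic pseudogene, and Gm10851 had none and were at least 1474-fold and 1956-fold higher. Interferon-gamma response genes were higher in 30 of 34 cases with a median of 1.57 (1.29 to 1.42 over the parts), and Iigp1 had 690.5 against 12.2 CPM. Toll-like receptor and NF-kB genes were higher in 28 of 32 cases with a median of 2.13 (1.53 to 2.95, percentile 100), or 2.35 with genes absent from a group set at their bound. Ribosome biogenesis and MYC target genes were higher in 31 of 33 cases, with a median of 0.51 (0.29 to 0.65, percentile 100), among them Gnl3, the gene of nucleostemin, at 457 against 238 CPM. The ranked lower genes were Myl10, Plpp6, A130014A01Rik, Tmem184c, Lax1, Hid1, Pbx3, Pbxip1, Plk2 and Klf1, with log2 folds from -2.69 to -3.45. A130014A01Rik is annotated as a long noncoding RNA of a bidirectional promoter, so the origin of its reads is uncertain. FoxO, autophagy and lysosome genes had a median of -0.41 with 25 of 31 lower (-0.54 to -0.29), and the FoxO gene Foxo3 had 28.7 against 63.3 CPM. Calcium channel, pump and store genes had a median of -0.13 (-0.24 to 0.056, percentile 42.8). Megakaryocyte and platelet genes were lower in 12 of 15 cases with a median of -0.78 (-1.29 to -0.55, percentile 0), and erythroid genes had a median of -1.25 (-1.61 to -0.77).

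The LPS effect was then compared between p27 high and p27 negative cells by the difference of the log2 folds. Type I interferon response genes differed little, with a median difference of -0.19 (-0.7 to 0.14, percentile 0.27) and 16 of 40 more strongly higher in p27 high cells. Among the members were Rsad2 at 2.88 and Cmpk2, a mitochondrial nucleotide kinase gene, at 2.77. Mx1 stood at -2.26, but at 0.16 without the top cell of each group, and its parts ran from -3.72 to 0.42. Ly6a had a difference of -1.29 (-2.31 to -0.6), its LPS log2 fold being smaller in p27 high cells. FoxO, autophagy and lysosome genes had a median of 0.45 (0.22 to 0.5, percentile 99.95) with 21 of 31 positive, Map1lc3b among them at 0.83. Calcium channel, pump and store genes had a median of -0.36 (-0.52 to -0.25, percentile 0.24) with 22 of 36 negative, including the IP3 receptor gene Itpr3 at -3.55, whose parts ran from -5.13 to 1.72. In cells numbered 33 to 96 the FoxO median was 0.16 and the calcium median -0.14. The ranked genes were Spata2l, A130014A01Rik, Ms4a4c, Ackr1 and Agtpbp1 on the positive side, with differences from 3.57 to 5.63. On the negative side they were Zfp30, Gpr65, Snx32, Plekha3 and Tbc1d24, with differences from -1.67 to -6.29. The smallest of these, that of Tbc1d24, lay outside its part values of -4.11 to -2.8 and was -2.93 without the top cell of each group.

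Across genes, the p27 high against p27 negative log2 folds of control and of LPS cells, which share no libraries, had a Pearson r of 0.505 and a Spearman rho of 0.408 over 8046 genes. The LPS log2 folds of p27 high and of p27 negative cells, which share none either, had an r of 0.464 and a rho of 0.35 over 8046 genes. Both are correlations across genes, and genes are not independent replicates.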

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

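All tests of explanations given here were chosen after the result they concern had been seen.

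p27 high cells held 10.3 G2/M genes per cell at 1 to 4 reads without thinning in control and 9.4 under LPS, but 3.04 and 2.94 at 5 reads or more, and the few reads may belong to other cells of the same table or to low transcription in the cells themselves. To test this, genes held by 1 dominant cell were traced at 1 to 4 reads in the other cells, and 3 definitions of such genes were tried in turn. With at least 500 reads and 90% of the table's reads in 1 cell, 1 gene per table remained, and its reads lay in 3.32% of cells of the same and 8.36% of the other table in control (ratio 0.397), and in 3.28% and none under LPS, with 15.3 and 15.2 G2/M genes per cell predicted. With at least 200 reads in 1 cell and under 5 in all others, 27 control and 19 LPS genes gave 2.21% against 1.85% (ratio 1.2) and 1.96% against 0.677% (ratio 2.89), predicting 18.2 and 17.1 genes, and with the other table also under 5 reads the ratios were 2.17 and 6.95 over 12 and 7 genes, predicting 17.6 and 12.7. Stray reads and low transcription cannot be told apart here, since the predictions exceed what was seen while the ratio depends on the definition.

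Dormancy genes were lower under LPS in every p27 class, and a larger share of reads taken by interferon genes might lower all other genes. TMM factors, which remove such a shift, left medians of -0.39 in p27 high and -0.73 in p27 low cells, with SDs over the parts of 0.157 and 0.268, which argues against it as the whole source there, while in p27 negative cells the median of -0.27 lay within its SD of 0.281 of 0. Progenitors that enter the gate through a higher Sca-1 level might bring progenitor genes, whose medians under LPS were -0.18, -0.39 and -0.64 in the 3 classes. The highest part median was 0.19. The list includes Cd48, whose protein the gate excludes, so progenitors inside the gate need not carry Cd48, but the gate excludes no other member. The medians below 0 give no sign of such entry, but with a part median above 0 entry of progenitors stays open. A difference between the runs or plates of the 2 tables also stays open, since treatment and table coincide and the largest difference between parts of 1 group reached 1.29 times the LPS difference in p27 negative, 0.509 in p27 high and 0.477 in p27 low cells. An effect of LPS on the cells, the biological explanation that the design names, was not tested against these.

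Megakaryocyte and platelet genes were lower in p27 high than in p27 negative cells under both treatments, and a few cells with very many reads in the other groups might account for this. Without the top cell of each gene the median was -1.01 in control and -1.45 under LPS. At equal depth a read of Pf4 was found in 47.3% (36.9 to 57.9%) of LPS p27 high and 60.9% (50.1 to 70.9%) of LPS p27 negative cells and in 54.8% (43.5 to 65.7%) and 56.8% (46.3 to 67%) of the control cells, so the intervals overlap, and although the LPS shares with at least 5 reads without thinning of 30.1% (21 to 40.5%) and 59.8% (49 to 69.9%) did not, p27 negative cells had more reads, so a few cells with many reads stay open in both treatments. Platelets or their RNA attached to sorted cells should also bring Ppbp, Tubb1 and Clec1b. Of these 3 genes 1, Ppbp, was higher in p27 high cells than in both other classes in summed reads in both treatments. It had 11.5, 4.24 and 8.87 CPM in control and 11.6, 1.01 and 4.73 under LPS. However, 1 cell held 87.6% and 60% of the Ppbp reads of control and LPS p27 high cells. At least 5 reads without thinning lay in 3.57% of control p27 high against 4.3% and 5.26% of control p27 low and negative cells. Under LPS these shares were 7.53% against 2.22% and 3.26%, with overlapping intervals. Clec1b had 6.82, 2.79 and 9.33 CPM in control and 5.47, 0.144 and 0.0204 under LPS, and Tubb1 4.19, 0.164 and 0.481 in control and 0, 0.072 and 0.959 under LPS, values that mostly go against attached platelets, but no gene of the 3 had at least 5 reads in more than 7.53% of the cells of a group, so attached platelets stay open.

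Several effects had opposite directions in a pair of groups, in the sums and in all 3 parts, and these differences were not tested. They make up 4 of 186 combinations of 31 lists with 6 pairs of comparisons, and 12 combinations for genes. The genes searched were the 5 ranked each way for the difference of the LPS effect, in 1 pair, and the 10 always named, in 6 pairs. The ranked genes were picked for a large difference of 1 direction in all parts, so their opposite directions are partly selected for. Monocyte, macrophage and dendritic cell genes had a median log2 fold of p27 high against negative of -1.59 in control and 0.70 under LPS over 8 and 6 measured genes, and of p27 low against negative of -1.43 and 0.66 over 10 and 6, but both LPS medians lay within the central range of random lists (percentiles 91.8 and 94.9). With members of at least 10 CPM these medians were 0.27 and 0.51 for p27 high and -0.35 and -0.28 for p27 low cells, so the opposite directions were gone. Nuclear-encoded oxidative phosphorylation genes had a median LPS effect of 0.083 in p27 high cells, -0.045 in p27 low and -0.12 in p27 negative cells, all within the central range (percentiles 92.4, 63.3 and 16.6). With TMM factors these were 0.21, 0.11 and 0.0020, so the opposite signs depend on scaling to total reads. The LPS log2 fold in p27 high and in p27 negative cells was 4.07 and -1.27 for Spata2l, 1.85 and -3.45 for A130014A01Rik and 2.51 and -1.06 for Agtpbp1. It was -4.85 and 1.45 for Zfp30, -1.48 and 2.53 for Gpr65, -2.02 and 1.54 for Plekha3, and -0.62 and 1.06 for Tbc1d24. Cd48, whose protein the gate excludes, had 0.96 and -0.89, but it was found in 3.57% of control p27 high cells, where 1 cell held 77.3% of its reads, and in cells with at most 10% mitochondrially encoded reads the effect in p27 negative cells was 0.074, so its opposite direction did not hold. The p27 high against negative log2 fold of Cdkn1b was -0.13 in control and 0.52 under LPS. Ccnd1 had a p27 high against low log2 fold of -0.99 in control and 1.91 under LPS, and an LPS effect of 0.76 in p27 high and -2.14 in p27 low cells. At equal depth its reads were found in 19% of control p27 high and 22.6% of control p27 low cells. Under LPS the shares were 17.2% and 12.2%, and the intervals overlap, so these folds rest on reads of a minority of cells. Ccnd2 had a p27 high against low log2 fold of 0.32 in control and -0.39 under LPS.

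The spike-in counts, which no comparison used, carried a signal of their own. The number of gene reads per spike-in read was higher in p27 negative than in p27 high cells, by ratios of medians of 1.6, 1.81 and 1.8 in the 3 parts of control and 1.9, 1.72 and 2.19 in those of LPS cells. Over all kept cells the medians were 21.6 and 16.2 in control, a ratio of 1.34, and 46.2 and 24.9 under LPS, a ratio of 1.86. CPM scales each group to its own gene reads, so this difference does not enter the folds. The dormancy medians of p27 high against negative, 0.89 in control and 0.73 under LPS, therefore describe shares of reads. Counted per spike-in read these medians would be smaller, since p27 high cells had fewer gene reads per spike-in read. Whether p27 high cells held more of these transcripts per cell was not tested.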

How the results depend on the processing

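Each group is 1 sample and the labels pair no cells across groups, so no paired test was run. The cell numbers share a structure across the p27 classes, since control cells 1 to 32 had median spike-in reads of 49264, 51979.5 and 59247 in p27 high, low and negative cells against 10392.5 to 12534 in the other control parts. The folds within single parts compare the p27 classes within these blocks of numbers. Depth limits what a few reads show, since the kept cells with at least 200000 reads numbered 47, 54, 70, 71, 65 and 83 in control p27 high, low and negative and LPS p27 high, low and negative cells. The spread between animals is not known, so every value describes 1 sample per group. Alternatives were planned before the data were examined except for cells numbered 33 to 96, which were added because gene reads per spike-in read were low in control cells 1 to 32. A list median was taken to move when it differed by more than the SD of the 3 parts, a share when it left its interval, by a rule set after list values had been seen.

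For the 15 main list medians 225 values were computed, of which 203 moved by less than that SD, 8 moved up and 14 moved down. The parts that set the SD are among these values, and most alternatives share most of their reads, so this rule favours little movement. The dormancy median of p27 high against low in control counted as not moved at 0.14 in cells 1 to 32, against 0.40 in all cells. In 1 value the sign changed, the difference of the LPS effect on type I interferon genes, which was 0.14 in cells 1 to 32 and -0.19 in all cells. In cells 33 to 64 the G2/M median of p27 high against negative was -5.38 in control and -4.98 under LPS, that of p27 low against negative under LPS -5.54, and the dormancy median of p27 high against negative 1.2 in control and 0.33 under LPS. There the LPS effect on dormancy genes was -0.70 in p27 high and -0.59 in p27 low cells. In cells 1 to 32 the G2/M median of p27 low against negative was -5.00 in control and -5.18 under LPS, and the dormancy median of p27 high against low under LPS 1.13. In cells 65 to 96 the LPS effect on type I interferon genes was 2.20 in p27 high and 3.16 in p27 negative cells, and its difference -0.70. Without the top cell of each gene the G2/M median was -4.37 for p27 low against negative in control, and under LPS -5.08 for p27 high and -5.32 for p27 low against negative. With cells weighted equally it was -4.30 for p27 high against negative under LPS. With 5 CPM added it was -3.71 for p27 high and -3.92 for p27 low against negative under LPS, and the interferon median in p27 negative cells 2.48, and with 0.1 CPM added the p27 low G2/M median under LPS was -5.29, since the added value sets how far low levels can fall. In cells with at least 200000 reads the interferon median in p27 low cells was 3.51. In cells 33 to 96 the dormancy median of p27 high against negative was 1.03 in control and 0.54 under LPS. For the changes by part, by top cell, by weighting and by read limit the cause was not tested.

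The share of cells with at least 5 G2/M genes depended on depth and on the limit by construction. Thinned to 200000 reads it was 97.9% in control p27 high, 88.9% in control p27 low, 90.1% in LPS p27 high and 93.8% in LPS p27 low cells, with 97.1% in control and 98.8% in LPS p27 negative cells. Without thinning these were 98.8%, 100%, 100% and 100%, with 98.9% in p27 negative cells of both treatments, so the classes were no longer apart. With at least 5 reads the shares in p27 high and low cells were 20.2%, 15.1%, 17.2% and 13.3%, and 90.5% in control p27 negative cells. With at least 3 genes they were 97.6%, 90.3%, 86% and 87.8%, and 98.9% in LPS p27 negative cells, and with at least 8 genes 28.6%, 25.8%, 19.4% and 12.2%, and 89.5% in control p27 negative cells. The median number of genes per cell was 5279, 5361, 6076, 5320, 5140 and 6161 at 200000 reads in the 6 groups, in the order given above, and 5447.5, 5612, 6598, 5675, 5664.5 and 6940.5 without thinning. With at least 5 reads per gene it was 3214, 3431, 4558, 3555 and 3518.5 in the first 5 of these groups.

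Among 295 other list medians 334 of 4425 values moved up and 310 down, and 378 had the other sign, 3 of them for a median outside the central range of random lists with 1 sign in all parts. With members of at least 10 CPM the monocyte, macrophage and dendritic cell median of p27 high against negative in control was 0.27, and with members of any read the LPS effect in p27 negative cells was 0.029 for B lineage and -0.034 for mast cell and basophil genes, since the members counted differ. Among 380 named gene folds 350 of 4940 values moved up and 330 down, and 98 had the other sign, 2 of them for a gene with 1 direction in all parts and in the mean of per-cell CPM. With at most 10% mitochondrially encoded reads the LPS effect on Cd48 in p27 negative cells was 0.074. That limit left 93 of 95 control and all 92 LPS p27 negative cells, so the change came from the control cells left out. In cells with at least 200000 reads the difference of the LPS effect on Slamf1 was 0.15, and the cause of that change was not tested. Of 2106 values of shares of cells with a gene 602 moved up and 131 down.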

Other observations

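Some other genes differed between LPS and control. Plac8, a gene of interferon-responsive and myeloid progenitor cells, had 213 against 63.6 CPM in p27 high, 958 against 143 in p27 low and 241 against 88.1 in p27 negative cells. Cdkn1a, the gene of the CDK inhibitor p21, was higher under LPS with log2 folds of 3.17, 1.75 and 2.11, although 1 cell held 80.6% of the control reads in p27 high and 60.7% in p27 negative cells. Plk2, like Cdkn1a a p53 target gene, was lower with -2.65, -2.81 and -3.0, although 1 cell held 89.9% of the LPS reads in p27 low cells. Selp, the gene of P-selectin, had 141 against 19.8 CPM in p27 high and 65.5 against 12.2 in p27 negative cells. Hdc, the histidine decarboxylase gene of histamine synthesis, had 80 against 0.553 CPM in p27 high, 26.9 against 0.789 in p27 low and 21.3 against 0.601 in p27 negative cells. It was detected in 11.8%, 12.2% and 17.4% of the LPS cells, and 1 cell held 45.4%, 43.6% and 37.9% of its reads.

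Genes of cytosolic ribosomal proteins were slightly higher in p27 high than in p27 negative cells, 36 of 43 in control with a median of 0.2 (0.086 to 0.26, percentile 96.8) and 36 of 43 under LPS with 0.18 (0.098 to 0.26, percentile 95.9), within the central range of random lists both times. The glycolysis regulator gene Pfkfb3 had 169.7 CPM under LPS against 20.8 in control p27 high cells, where 1 cell held 73.6% of the control reads, and 71.9 against 15.4 in p27 negative cells.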
